A study of Danio rerio with 12 samples.

How the data were processed

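Gene expression was measured in whole zebrafish (Danio rerio) embryos of the AB wild-type strain on 12 Agilent arrays, 1 per sample and with nothing pooled. Embryos of 24 or 72 hours post fertilisation (hpf) spent 3 h in 25 µM beclomethasone or in 0.1% DMSO, which makes 4 groups of 3 arrays. Total RNA was amplified and labelled with Cy3, per the labels' protocols, so that each array has 1 colour. The labels call the replicates triplicate experiments and do not say whether they came from separate clutches, so that every p-value measures only the spread between these samples.

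The scanner output of each array holds spot intensity values that the authors produced with Agilent Feature Extraction 10.7.1.1 on array design 026437, per the file headers. The processed intensity in those files was background-subtracted and corrected for spatial trends within each array, with low values replaced, and was not normalized between arrays, per the file headers. The authors also deposited a table of log2 values with 43663 probes per array. Per the submitters' processing notes, Agilent Feature Extraction and limma were used, without versions or steps. The columns of that deposited log2 table have medians of 7.37 to 7.38 and share a maximum of 19.2, which is the shape of values made equal in distribution between arrays. Its background correction and any centring of genes are not stated.

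The table's treatment labels were checked against the scanner arrays over 14927 probes above a raw log2 intensity of 8 on every array. Each of the 12 columns correlated best, across genes with each gene centred, with the scanner array of the same stage and replicate number but the other treatment (r between 0.993 and 0.998, against 0.658 to 0.826 for the array with its own label). Probes are not independent replicates. All results use the scanner arrays with their own labels. The deposited table was used as an alternative, once as labelled and once with each column joined to the array it matches.

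From the scanner arrays, log2 of the processed intensity was taken and each array's 75th percentile over its 43803 non-control spots subtracted. Control spots were left out, as were spots that the scanner software marked as uneven or outlying (14 to 79 per array). Spots of the same probe were averaged to 43603 probes. A probe was tested where it was well above background, by the scanner software's own test, on all 3 arrays of at least 1 group, which left 36187 probes. Gene symbols came from a table of RefSeq accessions, matched without versions. Of 26981 probes with a RefSeq accession, 25069 were named, for 12858 genes, and 1912 were not in the table. The other probes carry identifiers that no table at hand pairs with a gene, so that 18534 probes stayed unnamed. A gene with several probes was represented by its brightest one, which applied to 6955 of the 11963 genes tested. Among the genes named here, probes of tubb5 and of mcm5 passed the threshold at 24 hpf with opposite signs. Together with 13249 unnamed probes, and after those with missing values were dropped, 25205 genes and probes were tested.

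Differences were tested with limma 3.58.1 in R 4.3.3. A model with a mean for each of the 4 groups was fitted to all 12 arrays, which leaves 8 residual degrees of freedom, and the spread was moderated with eBayes. Contrasts were beclomethasone against DMSO at 24 hpf, at 72 hpf and averaged over both stages, the difference of the 2 treatment effects (72 hpf minus 24 hpf), and 72 against 24 hpf within DMSO. Adjusted p-values are Benjamini-Hochberg values over all genes and probes tested, and a call is an adjusted p below 0.05. Fold changes are given as log2 with the standard error (SE) from the fit, with 3 arrays per group. A gene not well above background on any array of the dimmer group has only a bound. It is the brighter group's mean over the dim group's mean of the higher of the array's lowest signal well above background and the gene's own signal, and is written as at least N-fold.

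The lists of 32 kinds of genes were written from general knowledge of zebrafish biology before the data were examined, as were the model, the threshold, the rule for naming genes and the alternatives, apart from 4 alternatives that the closing section names as chosen later. Lists with at least 5 measured genes were tested with camera from limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Each was tested again with a correlation estimated per list. Camera compares the moderated t-statistics of a list with those of the other genes and probes, so that its higher and lower are relative to these. Counts of calls in a list are given over all genes tested and, where so stated, adjusted over the list alone. The named genes are the 10 largest rises and falls per treatment contrast among calls whose groups do not overlap, the 5 largest of each sign for the difference between stages and for stage, up to 4 called genes per list and treatment contrast by size (2 per list for stage), and 14 genes of the glucocorticoid and Hedgehog pathways and of inflammation in any case, of which il1b was not tested because it did not pass the background filter. The text leaves out 2 genes that this rule picks.

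The number of arrays limits the precision. The steps were tested on simulated data in which 200 of the 25205 genes and probes were changed by known amounts. The noise was independent between genes and arrays, with each gene's residual spread the same in all groups. No uneven array, slide difference or pairing was put in, so that the shares below do not cover these features of the data. Far fewer genes were called than the 1586 to 16589 of the real comparisons. An adjusted p below 0.05 then takes a smaller unadjusted p, so that the shares do not give the sensitivity of the real comparisons. For the comparison at 24 hpf, 29.9% of 67 genes changed 1.5-fold, 68.7% of 67 changed 2-fold and 77.3% of 66 changed 4-fold were recovered, with 7 unchanged genes among 124 calls. At 72 hpf the shares were 32.8%, 55.2% and 86.4%, with 8 unchanged genes among 124 calls. For the difference between stages they were 16.4%, 53.7% and 77.3%, with 6 among 104. For both stages together they were 67.2%, 77.6% and 81.8%, with 8 among 159, and for stage 37.3%, 49.3% and 69.7%, with 2 among 106.

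The arrays lay on 3 slides, each scanned at its own time on 1 day, so that slide and scan are the same factor. Slide 1 held the 3 DMSO arrays of 24 hpf and beclomethasone replicate 1 of 24 hpf. Slide 2 held beclomethasone replicates 2 and 3 of 24 hpf and DMSO replicates 1 and 2 of 72 hpf, and slide 3 held DMSO replicate 3 and the 3 beclomethasone arrays of 72 hpf. With slide as a block, the treatment effect at a stage rests on the slide that holds both treatments of that stage, so that this value is also the value within that slide. At 24 hpf it compares 1 beclomethasone array with 3 DMSO arrays, and at 72 hpf 3 beclomethasone arrays with 1 DMSO array.

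Groups share replicate numbers. Whether these pair the arrays was checked by correlating, across genes, the deviations of same-numbered DMSO and beclomethasone arrays from their group means. At 72 hpf the 3 correlations were 0.53, 0.51 and 0.50, and every one being above 0.1 was the rule for pairing. At 24 hpf they were -0.09, 0.06 and -0.05, so that the rule was not met. The DMSO mean of that stage holds replicate 3, an uneven array described below, which enters every DMSO deviation there. The check therefore cannot exclude pairing at 24 hpf.

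Alternatives were normexp background correction (on the median spot signal and the median local background with an offset of 50, since no mean signal is in the files), quantile normalization, both together, centring on each array's median, the deposited table, no filter and a stricter filter on dim probes, marked spots kept, a median over a gene's probes, every probe on its own, only the arrays compared, eBayes with trend and robust, array weights, a replicate block, a slide block, a 2-fold minimum, an estimated correlation and fry for lists, and leaving out each array in turn. No 1 gene's level was set against another's.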

Results

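The 12 arrays measured transcripts of whole embryos at 2 stages, 24 and 72 hpf, after 3 h of beclomethasone or of its solvent, DMSO, with 3 arrays per group. Beclomethasone is a synthetic glucocorticoid that binds and activates the glucocorticoid receptor, a transcription factor that cortisol activates in the fish. Zebrafish embryos of 24 hpf are forming organs from the body axis, and embryos of 72 hpf have usually hatched and carry a working heart, retina and liver. Between 31210 and 37401 of the non-control spots were well above background on 11 of the arrays. On the twelfth, 24 hpf DMSO replicate 3, 16764 were. No array had a saturated spot (0 on each), and the 75th percentile of the signal lay between 574 and 1134 scanner units.

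The first principal component held 76.0% of the variance and separated the stages, and the next ones held 12.5% and 3.82%. Arrays of the same group correlated across genes at 0.992 to 0.995 for beclomethasone and 0.931 to 0.993 for DMSO at 24 hpf, and at 0.994 and 0.987 to 0.988 at 72 hpf. The low end at 24 hpf came from DMSO replicate 3. Its lowest signal was 42.8 units against 2.36 to 3.89 on the other 11 arrays. The lowest signal well above background was 215 against 11.8 to 19.5, and the spread of its negative controls was 175 against 8.28 to 13.8. Signals of weakly expressed genes are therefore too high on that array, which raises the DMSO mean of such genes at 24 hpf.

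**Figure D1:**
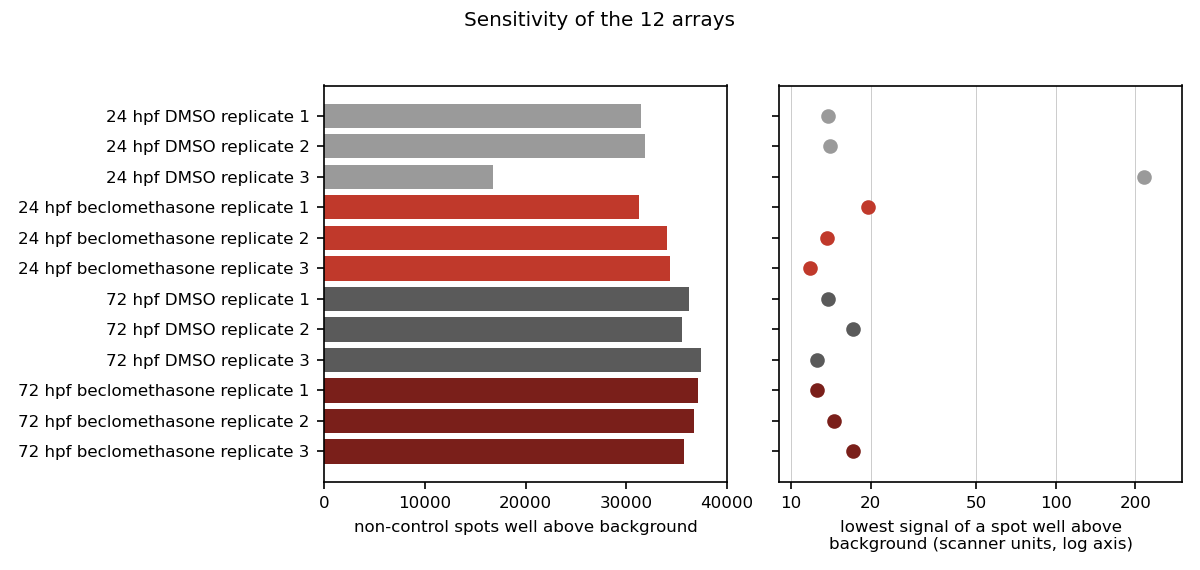
For each of the 12 arrays, the bars on the left give the number of non-control spots well above background and the points on the right the lowest signal of such a spot, in scanner units on a log axis. 24 hpf DMSO replicate 3 stands apart in both, at 16764 spots and 215 units.

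The comparison at 24 hpf asks which transcripts 3 h of beclomethasone changed in embryos that were forming their organs. The rises included known targets of the glucocorticoid receptor: fkbp5, whose product binds the receptor and dampens it, klf9, a transcription factor gene, and hsd11b2, whose product inactivates cortisol. Lists of sugar breakdown, red blood cell, muscle and liver genes passed as higher, and those of protein folding under stress and of chromatin as lower, at a preset correlation between genes. With an estimated correlation only the receptor targets passed, and these 6 lists had adjusted p-values between 0.0721 and 0.183. These directions use the treatment labels of the scanner arrays. The deposited table of log2 values carries the opposite treatment labels, and as labelled it turns the sign of 127 of the 128 calls named at this stage.

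Of 25205 genes and unnamed probes, 4831 were called at 24 hpf with limma, 2276 higher and 2555 lower in beclomethasone, and 2785 of them had a gene symbol. A change of at least 2-fold was found for 365 rises and 210 falls. The median of all log2 fold changes was -0.12, and it was -0.20 with each array centred on its median and 0.02 with quantile normalization, so that small falls at this stage lie near the middle of all genes. The split was 1830 higher and 4152 lower with median centring and 2252 and 7404 after normexp. With slide as a block, which leaves 1 beclomethasone array against 3 DMSO arrays, 891 were called, 586 higher and 305 lower. Leaving out 1 array changed the count to between 2204, without beclomethasone replicate 2, and 6309, without DMSO replicate 3, and it was 2968 without beclomethasone replicate 1. With only the 24 hpf arrays in the fit, 74 of the 128 calls named at this stage passed.

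The gene hsd11b2 rose by 3.93 ± 0.12 (log2 fold change ± SE, adjusted p = 1.93e-07). The rise of fkbp5 was called (adjusted p = 0.00927), and its size is not given, since it was well above background in DMSO on replicate 3 alone. For klf9 the rise was at least 5.91-fold (adjusted p = 0.00613), with no DMSO array well above background. Other large rises were those of the kinase gene stk35 (3.70 ± 0.16, adjusted p = 2.97e-06), the fast muscle troponin gene tnni2b.2 (3.68 ± 0.11, adjusted p = 1.93e-07) and the clock repressor gene nr1d2a (3.52 ± 0.17, adjusted p = 4.66e-06). The oxygen sensor gene egln3 (3.41 ± 0.37, adjusted p = 5.78e-04) and the protease gene prss60.1 (3.14 ± 0.19) followed. The prostaglandin carrier gene slco2a1 rose at least 3.07-fold at its brightest probe, with -0.88 at its other one, and agxtb, which encodes an enzyme of glyoxylate metabolism, at least 2.4-fold. Genes for glutamate decarboxylase (gad3, -1.70 ± 0.11, adjusted p = 2.43e-05), the envoplakin of skin (evpla, -1.25 ± 0.14) and the chaperones dnaja1 (-1.20 ± 0.18) and hspa4a (-1.16 ± 0.12) fell, as did krt99 (-1.37 ± 0.28) and rbm12 (-1.15 ± 0.23). The falls of ubtd1a, etnk2, slc34a2aas and paqr5b, between -1.57 and -1.31, rested on DMSO replicate 3 for part of their size, since they were -0.85, -0.78, -0.82 and -0.74 without it. In the fit with the slide block, fkbp5 (adjusted p = 0.121), klf9 (0.100), agxtb (0.191), slco2a1 (0.124), ubtd1a (0.322), krt99 (0.139), dnaja1 (0.0618) and rbm12 (0.117) no longer passed. The values of ubtd1a, krt99, dnaja1 and rbm12 were -1.39, -1.21, -1.19 and -1.10 there, close to those without the block, so that these lost calls do not show a smaller change. Of the 128 calls named at this stage, 63 passed with that block and 0 turned their sign.

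Of 22 measured genes fixed as glucocorticoid receptor targets, 13 rose, 0 fell and 9 were not called (14 and 1 adjusted over the list alone). The list rose as a whole, with a mean of 1.2 (camera adjusted p = 2.58e-09) and 1.22 with slide as a block, and it passed with an estimated correlation too (adjusted p = 0.00520). The leucine zipper gene tsc22d3, which mediates anti-inflammatory effects of glucocorticoids, rose by 1.31 ± 0.18 (adjusted p = 0.00161), sgk1 by 0.57 ± 0.06 (adjusted p = 5.36e-04), and ddit4, a brake on growth signalling, by 2.25 ± 0.40 (adjusted p = 0.00599). The clock gene per1a (-0.42 ± 0.27, adjusted p = 0.298) and the gluconeogenic gene pck1 (1.66 ± 0.56, adjusted p = 0.068) were not called, although the other probe of pck1, at 3.56, was. At its brightest probe, the signal of pck1 on DMSO replicate 3 was not well above background, yet higher than on the other DMSO arrays. The missing call of pck1 therefore does not show an unchanged gene. In the stress axis list of 14 genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.396). The receptor's own gene nr3c1 fell by 0.44 ± 0.09 (adjusted p = 0.00857) at its brightest probe, the only 1 of its 3 that was called, avp rose by 0.34, and oxt was not well above background in either group, so that no fold is given. The brain hormone gene crhb (adjusted p = 0.235) and the pituitary hormone gene pomca (adjusted p = 0.12) were not called.

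Lists of energy metabolism were higher at 24 hpf at the preset correlation. Of 28 glycolysis genes, 19 rose and 0 fell (21 and 0 adjusted over the list alone). The risers included the phosphofructokinase gene pfkmb (1.69 ± 0.17), gpia (1.35 ± 0.12) and pgam1a (1.22 ± 0.11). The list's mean was 0.48 (camera adjusted p = 6.99e-13; adjusted p = 0.0721 with an estimated correlation) and 0.56 with slide as a block. Of 10 gluconeogenesis genes 4 rose and 0 fell (5 and 1 adjusted over the list alone), with pck2 at 1.62 ± 0.15 (camera adjusted p = 0.00174; adjusted p = 0.0727 with an estimated correlation). In the list of 34 genes that handle foreign compounds, 13 rose and 2 fell (15 and 4 adjusted over the list alone; camera adjusted p = 2.26e-04; adjusted p = 0.0721 with an estimated correlation). The cytochrome genes cyp1a (2.19 ± 0.21) and cyp1c2 (2.07 ± 0.19) of the aryl hydrocarbon response were among the risers. Of 38 lipid and cholesterol genes 7 rose and 4 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.0262; adjusted p = 0.390 with an estimated correlation, and 0.0707 without DMSO replicate 3). Of its members, msmo1 rose by 2.09 ± 0.28 and lss by 1.49 at its brightest probe, with -0.05 at its other probe. The fall of pparg (-1.64) was not called without DMSO replicate 3. The circadian clock list of 30 genes had 8 rises and 2 falls (9 and 3 adjusted over the list alone; camera adjusted p = 0.00166; adjusted p = 0.0721 with an estimated correlation). Its largest rises after nr1d2a were those of cry4 (2.04 ± 0.13) and tefb (2.03 ± 0.29).

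Lists of some tissues were higher as well, at the preset correlation only. Of 17 erythroid genes 11 rose and 0 fell (13 and 0 adjusted over the list alone), with a mean of 0.62 (camera adjusted p = 1.77e-08; adjusted p = 0.134 with an estimated correlation) and 0.65 with slide as a block. They included the carbonic anhydrase gene cahz (1.04 ± 0.12), nt5c2l1 (1.23 ± 0.13) and gata1a (0.95 ± 0.27, adjusted p = 0.0376), the regulator of red cell fate. Of 35 skeletal muscle genes 15 rose and 1 fell (18 and 2 adjusted over the list alone; camera adjusted p = 5.37e-07; adjusted p = 0.117 with an estimated correlation), with tnni2a.4 at 1.26 ± 0.18 and tpma at 0.69. The slow myosin gene smyhc2 rose by 1.36 at its brightest probe and was -0.72 as the median over its probes. Of 12 heart muscle genes 6 rose and 0 fell (7 and 0 adjusted over the list alone), with actc1a at 1.12 ± 0.15 and gata5 at 0.75 (camera adjusted p = 4.16e-05; adjusted p = 0.0721 with an estimated correlation). Of 22 liver genes 9 rose and 0 fell (12 and 1 adjusted over the list alone), with uox at 1.52, igfbp1a at 1.51 and plg at 1.02 (camera adjusted p = 5.20e-06; adjusted p = 0.134 with an estimated correlation).

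Of 25 genes of ionocytes, the skin cells that move salts, 8 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 6.25e-04; adjusted p = 0.0980 with an estimated correlation). The sodium pump gene atp1a1a.3 rose by 1.64 ± 0.14 and the ionocyte regulator foxi3a by 1.24, and the parathyroid hormone gene pth1a fell by 1.21. Of 22 genes of epidermis and hatching gland 7 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 6.15e-06; adjusted p = 0.163 with an estimated correlation), with klf17 at 1.03 ± 0.11 and krt92 at 0.79. Of 22 blood vessel genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.00916; adjusted p = 0.144 with an estimated correlation, and 0.0615 without DMSO replicate 3), with etsrp at 0.76 and flt4 at 0.47. Of 14 leukocyte genes 3 rose and 0 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.0360; adjusted p = 0.255 with an estimated correlation, and 0.0707 without DMSO replicate 3). Their mean of 0.02 was -0.06 with median centring and -0.07 after normexp, but 0.16 without DMSO replicate 3, 0.25 with slide as a block and 0.27 with quantile normalization. The neutrophil gene lyz rose by 0.60, and mpx by 0.42 at its brightest probe, which turned to -0.17 after normexp. Of 16 segmentation genes 1 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.0181; adjusted p = 0.228 with an estimated correlation, and 0.134 without DMSO replicate 3). The riser was dlc, by 0.26.

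Other lists held more falls than rises. Of 30 genes of heat shock and the unfolded protein response, 16 fell and 2 rose (18 and 2 adjusted over the list alone), with a mean of -0.34 (camera adjusted p = 4.22e-05; adjusted p = 0.183 with an estimated correlation) and -0.30 with slide as a block. The chaperone gene hsp90aa1.2 fell by 1.13 ± 0.14 and the stress regulator atf4b by 0.69 at their brightest probes, and each has a probe that went up, by 0.19 and 0.33. The gene chac1, which degrades glutathione, rose by 0.65 ± 0.12. Of 19 chromatin genes 9 fell and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 4.82e-05; adjusted p = 0.0980 with an estimated correlation). They include ezh2 (-0.82 ± 0.08) and suz12a (-1.06) of the Polycomb complex and the methyltransferase gene dnmt3ba (-0.46). Of 34 cell cycle genes 9 fell and 0 rose (9 and 0 adjusted over the list alone), with ccne1 at -0.82 ± 0.10, cdk2 at -0.63 and mcm3 at -0.56, and the list as a whole did not pass (camera adjusted p = 0.0652), though it did with median centring (-0.22, adjusted p = 0.0159) and with quantile normalization (-0.07, adjusted p = 0.0429). Of 71 ribosomal protein genes 2 rose and 4 fell (0 and 0 adjusted over the list alone), with rpl26 at -0.31 and rpl6 at 0.32. The mean of -0.11 had a camera adjusted p of 0.0183 (adjusted p = 0.701 with an estimated correlation, and 0.383 with slide as a block), and it turned to 0.06 with quantile normalization.

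Genes of growth arrest and protein turnover moved both ways. Of 23 cell cycle inhibitors and p53 targets 7 rose and 3 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.0510, but 0.0388 with median centring and 0.00519 after normexp), with gadd45ba at 1.59 ± 0.14, cdkn1ba at 1.27 and sesn2 at -0.77. Of 18 genes of protein turnover and muscle atrophy 5 rose and 2 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.0346; adjusted p = 0.117 with an estimated correlation), among them the translation repressor gene eif4ebp3 (1.57 ± 0.08). Of 22 inflammation genes 3 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.545). The factor gene rel rose by 2.49 ± 0.17 and the cytokine brake socs3a by 2.17 ± 0.29, nos2b fell by 1.61 ± 0.24, and the protease gene mmp9 was not called (adjusted p = 0.346). Of 23 immediate early genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.143, and 0.0374 after normexp), led by nr4a1 (2.36 ± 0.10) and fosab (2.01). Of 24 Hedgehog pathway genes 4 rose and 0 fell (3 and 0 adjusted over the list alone), by 0.44 for nkx2.2b (-0.02 at its other probe) and 0.34 for sufu. That list passed (camera adjusted p = 0.0250; adjusted p = 0.276 with an estimated correlation, 0.0626 with slide as a block and 0.188 without DMSO replicate 3), and its mean of 0.07 was near 0 with median centring. The pathway target gli1 was not called (adjusted p = 0.143).

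Altogether 17 lists passed as higher and 3 as lower at 24 hpf with the preset correlation, 21 lists with slide as a block and 15 without DMSO replicate 3, and 1 list, the receptor targets, with an estimated correlation. With quantile normalization the lists of Hedgehog (adjusted p = 0.102), vessel (0.0570), leukocyte (0.101), lipid (0.101) and segmentation genes (0.0570) did not pass, and after normexp those of leukocytes (0.116) and ribosomes (0.40). Another split of the same 6 arrays gave 18 lists, so that the number of lists by itself says little.

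**Figure D2:**
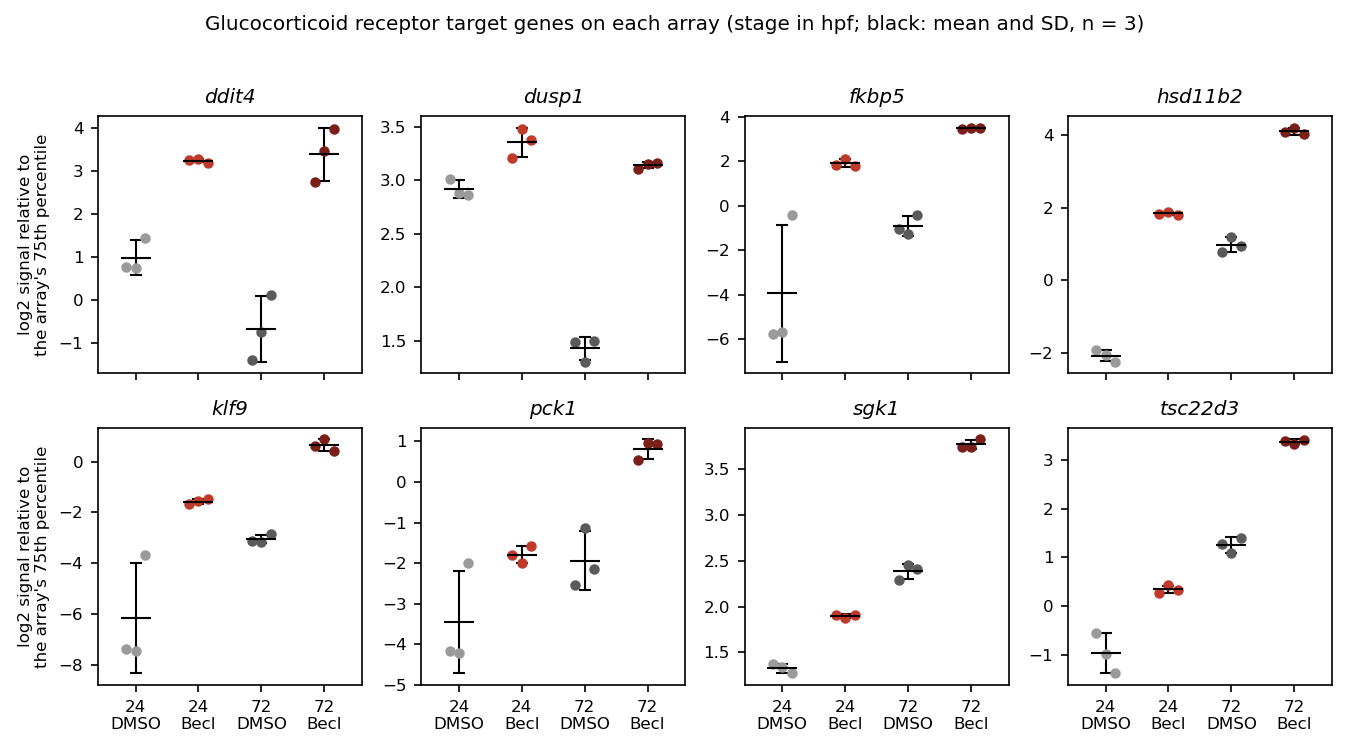
For 8 glucocorticoid receptor targets, the points give the log2 signal relative to the array's 75th percentile on each of the 12 arrays, with the mean and SD of 3 arrays in black. The beclomethasone arrays lie above the DMSO arrays of the same stage for fkbp5, klf9, hsd11b2, ddit4, dusp1, tsc22d3, sgk1 and pck1 at both stages. For pck1 the difference at 24 hpf was not called (adjusted p = 0.068). Its highest DMSO signal at that stage is that of replicate 3, which was not well above background.

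The comparison at 72 hpf asks the same of older embryos. The known receptor targets fkbp5, klf9, hsd11b2 and ddit4 rose again, and rhcga, which encodes an ammonia transporter of skin and gill, had the largest rise. The replication helicase genes mcm2 and mcm5 were among the 15 of 34 cell cycle genes that fell, while 0 rose and 19 were not called. The lists of circadian clock and protein turnover genes rose, also with an estimated correlation. The list of lipid and cholesterol genes did so only at the preset one (adjusted p = 0.151 with the estimate), whereas the lists for muscle, lens, retina, cartilage and pancreas held almost no call.

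At 72 hpf 2579 genes and probes were called, 1210 higher and 1369 lower, and 1532 had a symbol. At least 2-fold were 401 rises and 92 falls, and the median of all log2 fold changes was 0.00. With slide as a block, which leaves 3 beclomethasone arrays against 1 DMSO array, 766 were called, 485 higher and 281 lower. The replicate numbers paired the arrays at this stage, and with a replicate block within stage 2046 were called. Leaving out 1 array gave between 1512, without beclomethasone replicate 2, and 2379, and the count was 1575 without beclomethasone replicate 3 and 1714 without DMSO replicate 1.

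The gene rhcga rose by 4.91 ± 0.46 (adjusted p = 1.58e-04), ddit4 by 4.05 ± 0.40 (adjusted p = 2.22e-04), and egln3 by 3.79 ± 0.37 (adjusted p = 2.11e-04). Smaller SEs went with the integrin gene itga6b (3.49 ± 0.15, adjusted p = 1.81e-06) and hsd11b2 (3.13 ± 0.12, adjusted p = 1.43e-06). Larger SEs went with fkbp5 (4.40 ± 1.17, adjusted p = 0.0432), klf9 (3.68 ± 0.83, adjusted p = 0.0206) and the bile acid synthesis genes cyp8b1.3 (4.46 ± 0.84) and cyp8b1.2 (3.37 ± 0.85). The cytochrome gene cyp2k6 rose at least 8.02-fold, with no DMSO array well above background. Falls were those of abrab, an actin-binding muscle gene (-2.54 ± 0.10, adjusted p = 1.43e-06), the glycan synthesis gene b3gnt3.1 (-2.09 ± 0.16), jac10 (-1.81 ± 0.28), ntmt2 (-1.63 ± 0.18), rbm12ba (-1.51 ± 0.18), krt99 (-1.47 ± 0.28) and emp3b (-1.46 ± 0.15). The genes ppp1r27b, ripply2 and b3gnt3.3 were not well above background in beclomethasone and fell at least 3.83-fold, 2.02-fold and 1.54-fold. The slide block left fkbp5 (adjusted p = 0.447), klf9 (0.292), cyp8b1.3 (0.187) and cyp2k6 (0.217) uncalled, with fkbp5 at 3.91, klf9 at 3.51 and cyp8b1.3 at 4.22. The SEs of fkbp5 and klf9 come from the 24 hpf DMSO arrays, with SDs of 3.07 and 2.17 against at most 0.44 and 0.24 in the 72 hpf groups, so that these lost calls do not show a weaker response at 72 hpf. The replicate block within stage left fkbp5 (0.0868), ppp1r27b (0.0802), ripply2 (0.0579), cyp8b1.2 (0.0506) and krt99 (0.0529) uncalled. Of the 96 calls named at 72 hpf, 50 passed with the slide block and 81 with the replicate block within stage, and 0 turned their sign with either.

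Of the 22 receptor targets 16 rose and 0 fell (19 and 0 adjusted over the list alone), with a mean of 1.58 (camera adjusted p = 4.70e-21; adjusted p = 2.43e-04 with an estimated correlation) and 1.51 with slide as a block. The rises of tsc22d3 (2.12 ± 0.18, adjusted p = 7.17e-05), sgk1 (1.39 ± 0.06, adjusted p = 2.15e-06) and pck1 (2.75 ± 0.56, adjusted p = 0.0131, and 0.174 with slide as a block) were called, and per1a was not (0.65 ± 0.27, adjusted p = 0.203). In the stress axis list 0 genes rose and 2 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.226). The falls were those of crhb, which drives the stress hormone axis, by 0.48 ± 0.10 (adjusted p = 0.0177, and 0.0837 with the replicate block within stage), and the steroid synthesis gene cyp17a1 by 0.88 ± 0.15. The genes nr3c1 (adjusted p = 0.16) and pomca (-0.93 ± 0.35, adjusted p = 0.157) were not called. The SE of pomca comes largely from the 24 hpf DMSO arrays, with an SD of 0.86 against at most 0.24 in the 72 hpf groups. The missing call therefore does not show an unchanged gene. In the deposited table, with its opposite labels, pomca passed in limma at 72 hpf (0.89, adjusted p = 0.0191).

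Of 34 cell cycle genes 15 fell and 0 rose (22 and 0 adjusted over the list alone), with a mean of -0.39 (camera adjusted p = 1.05e-13; adjusted p = 0.0452 with an estimated correlation) and -0.41 with slide as a block. The helicase genes mcm2 (-1.18 ± 0.07), mcm5 (-1.15 ± 0.06), mcm3 (-1.10 ± 0.08) and mcm6 (-1.08 ± 0.07) led it. Of 19 chromatin genes 8 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 1.69e-07; adjusted p = 0.0452 with an estimated correlation), with the DNA methylation genes dnmt1 at -0.81 ± 0.06 and uhrf1 at -0.74. Of 23 cell cycle inhibitors and p53 targets 11 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 2.24e-06; adjusted p = 0.152 with an estimated correlation), with gadd45ba at 2.19 ± 0.14 and bbc3 at 0.95. Of 18 protein turnover genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 1.72e-05; adjusted p = 0.0112 with an estimated correlation). The translation repressor gene eif4ebp3l rose by 1.65 ± 0.07 and the muscle ubiquitin ligase gene trim63b by 1.0 ± 0.15.

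Of 30 clock genes 11 rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 1.24e-06; adjusted p = 0.0112 with an estimated correlation). The repressor genes nr1d2a and bhlhe41 rose by 2.23 ± 0.17 and 1.88 ± 0.13, and nr1d1 by 1.60 (adjusted p = 0.0281, and 0.0656 with the replicate block within stage). Of 38 lipid and cholesterol genes 11 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 1.45e-06; adjusted p = 0.151 with an estimated correlation), with the sterol genes insig1 (2.11 ± 0.13) and cyp51 (1.96 ± 0.14). Of 34 genes that handle foreign compounds 9 rose and 1 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.0116; adjusted p = 0.164 with an estimated correlation), with sult2st1 at 1.49 and hmox1a at 1.44. Of 23 immediate early genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 5.26e-04; adjusted p = 0.295 with an estimated correlation). The flow-responsive gene klf2a rose by 1.83 and the phosphatase gene dusp1, itself a receptor target, by 1.71 ± 0.09. Of 30 heat shock and unfolded protein genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0207; adjusted p = 0.524 with an estimated correlation, and 0.0783 after normexp), with chac1 at 1.79 ± 0.12, hsp70l at 1.21 and trib3 at 0.73. In glycolysis 2 of 28 genes rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.0200; adjusted p = 0.524 with an estimated correlation, 0.0571 without 24 hpf DMSO replicate 3 in the fit, 0.0625 with median centring and 0.0750 after normexp). They were hk2 (0.76) and pgam1a (0.46), which was not called with the replicate block within stage (adjusted p = 0.0691).

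The other lists did not pass at 72 hpf, and single members did. In gluconeogenesis 3 of 10 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.208), with pck2 at 1.39. In inflammation 3 of 22 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.684), with socs3a at 2.96 ± 0.29 and the cytokine gene tnfb at -1.06. The protease gene mmp9 was not called (adjusted p = 0.777). In the leukocyte list 1 of 14 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.182), with the macrophage gene mpeg1.1 at -0.95. In Hedgehog signalling 4 of 24 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.133, and 0.0146 with slide as a block), with sufu at 0.86 ± 0.05 and shhb at -0.33. The target gli1 was not called (adjusted p = 0.305). In the liver list 2 of 22 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.0642, and 0.0146 with the replicate block within stage). Both encode insulin-like growth factor binding proteins, igfbp1b (2.98 ± 0.42) and igfbp1a (1.31). Among 17 erythroid genes 0 rose and 2 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.779), with gata1a at -1.21 ± 0.27. In the ionocyte list 4 of 25 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.178), and that fall, of pth1a, was at least 1.53-fold. Of 22 epidermis genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0724), with tp63 at 0.84. Of 22 vessel genes 3 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.182), with the receptor gene kdr at 0.90. No gene was called among heart muscle, cartilage, retina, lens and pancreas lists, where limma gave 0 calls, and 1 of 35 skeletal muscle genes fell, myf5 by 0.43.

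At 72 hpf 9 lists passed as higher and 2 as lower, 14 passed with slide as a block and 5 with an estimated correlation. Another split of the same 6 arrays gave 19 lists.

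**Figure D3:**
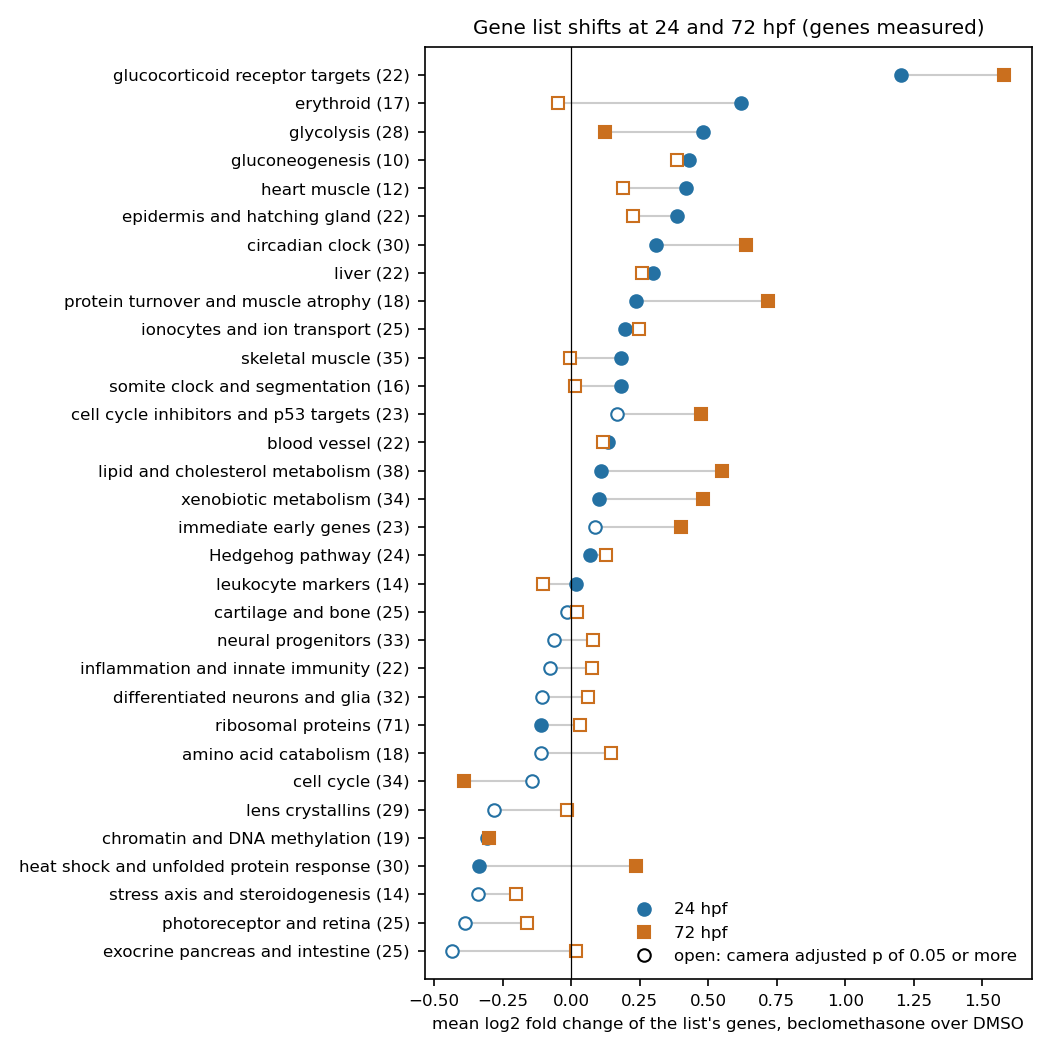
For each of 32 gene lists, with the number of genes measured in brackets, the circle gives the mean log2 fold change of beclomethasone over DMSO at 24 hpf and the square that at 72 hpf, and open symbols mark a camera adjusted p of 0.05 or more. Receptor targets are highest at both stages (1.2 and 1.58), erythroid genes are at 0.62 and -0.05, and heat shock genes at -0.34 and 0.24.

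The difference of the treatment effects asks where the response depended on stage. At the preset correlation, the lists of erythroid, muscle, heart and glycolysis genes shifted lower at 72 hpf than at 24 hpf relative to DMSO, and those of heat shock and of lipid and cholesterol genes higher. None of them passed with an estimated correlation (lowest adjusted p = 0.170), and the lipid list did not with slide as a block. The ammonia transporter gene rhcga and the integrin gene itga6b were called at 72 hpf and not at 24 hpf, and their difference passed too. The erythroid regulator gata1a rose at 24 hpf and fell at 72 hpf.

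With limma 1586 genes and probes differed in their response, 647 with a higher and 939 with a lower effect at 72 hpf, and the median difference over all genes was 0.11. The split was 1012 higher and 857 lower with median centring and 4396 and 1627 after normexp. The count was 67 with slide as a block, 848 with the replicate block within stage, and between 663, without 24 hpf beclomethasone replicate 2, and 3069, without 24 hpf DMSO replicate 3, when 1 array was left out. Leaving out 24 hpf beclomethasone replicate 1 gave 842, 72 hpf DMSO replicate 2 gave 892, and each of the 72 hpf beclomethasone arrays gave 827, 723 and 777. Of the genes called at 24 hpf only, 760 of 3668 differed between stages, and of those called at 72 hpf only, 492 of 1416. Without 24 hpf DMSO replicate 3 the fit gave 1577 and 852 such genes and probes that differed.

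The largest differences toward 72 hpf among genes measured at both stages were 4.97 ± 0.65 for rhcga (adjusted p = 0.00378), 3.07 ± 0.21 for itga6b (adjusted p = 1.76e-04) and 3.02 ± 0.60 for igfbp1b (adjusted p = 0.0202). For cyp8b1.3 and cyp2k6 the fit gave adjusted p-values of 0.0189 and 0.0113, but neither was well above background on any 24 hpf array, so that no size is given, and cyp8b1.3 had an adjusted p of 0.0644 with the replicate block within stage. The largest differences the other way were -3.65 ± 0.15 for tnni2b.2 (adjusted p = 1.81e-05), -3.35 ± 0.40 for the photoreceptor phosphodiesterase gene pde6ha (adjusted p = 0.00248) and -2.21 ± 0.25 for ntmt2 (adjusted p = 0.002). Next were -2.17 ± 0.38 for gata1a (adjusted p = 0.0132) and -1.98 ± 0.22 for b3gnt3.1 (adjusted p = 0.00181). With the slide block, itga6b (adjusted p = 0.00826) and tnni2b.2 (adjusted p = 0.00613) passed of these. Among receptor targets, sgk1 responded more at 72 hpf (0.81 ± 0.09, adjusted p = 0.00156) and hsd11b2 less (-0.80 ± 0.16, adjusted p = 0.0236). The differences of fkbp5 (adjusted p = 0.609) and klf9 (adjusted p = 0.651) were not called. In DMSO at 24 hpf klf9 was well above background on 0 arrays and fkbp5 on replicate 3 alone, so that no size is given.

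With camera 14 lists differed in their shift, 6 toward 72 hpf and 8 toward 24 hpf, and 0 held with an estimated correlation (lowest adjusted p = 0.170). Of 30 heat shock and unfolded protein genes 12 were higher and 0 lower in the difference (17 and 0 adjusted over the list alone; mean 0.57, camera adjusted p = 7.06e-08), and this list was lower at 24 hpf and higher at 72 hpf at the preset correlation. With an estimated one neither held (adjusted p = 0.183 and 0.524), and after normexp the one at 72 hpf did not (0.0783). Receptor targets (mean 0.38, camera adjusted p = 0.00627; mean 0.60 after normexp, and 0.23 with an adjusted p of 0.0584 without 24 hpf DMSO replicate 3) and lipid and cholesterol genes (0.44, adjusted p = 0.0216, and 0.347 with slide as a block) also shifted toward 72 hpf. So did protein turnover genes (0.48, adjusted p = 0.0404, 0.0554 with the replicate block within stage, and 0.160 with a mean of 0.26 without 24 hpf DMSO replicate 3) and p53 targets (0.31, adjusted p = 0.0479, and 0.114 with that block). After normexp the lists of protein turnover (adjusted p = 0.297), p53 targets (0.144), ionocytes (0.162) and ribosomal proteins (1.0) did not pass. The ribosomal shift of 0.14 (adjusted p = 0.00196) turned to -0.04 with quantile normalization (adjusted p = 0.448). In the other direction, 6 of 17 erythroid genes were lower and 0 higher (10 and 0 adjusted over the list alone; mean -0.67, camera adjusted p = 7.35e-08). For glycolysis 6 of 28 genes were lower and 0 higher (14 and 1 adjusted over the list alone; mean -0.36, adjusted p = 1.14e-07), and 8 of 34 cell cycle genes lower and 0 higher (8 and 0 adjusted over the list alone; mean -0.25, adjusted p = 6.51e-08). Skeletal muscle (-0.19, adjusted p = 1.70e-05), heart muscle (-0.23, adjusted p = 0.00196), leukocyte (-0.12, adjusted p = 0.0148) and liver genes (-0.04, adjusted p = 0.00563) shifted the same way. The leukocyte mean was -0.01 after normexp (adjusted p = 0.0837), -0.39 with quantile normalization (adjusted p = 0.0812) and -0.26 without 24 hpf DMSO replicate 3. The liver mean was -0.36 with quantile normalization, -0.30 with slide as a block and -0.19 without that array. The ionocyte list was lower by camera (adjusted p = 0.0200) with a median of -0.25 but a mean of 0.05. That mean was -0.25 without 24 hpf DMSO replicate 3, -0.15 with quantile normalization and -0.10 with slide as a block. With slide as a block 17 lists differed, and another split of the treatment labels within the stages gave 23.

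The average over both stages asks which genes respond when the 2 stages count equally. It holds fkbp5, klf9, hsd11b2 and the clock repressor gene nr1d2a as risers, and the genes mcm10 and ccne1 as fallers. Of the stress axis, single genes were lower on average, among them nr3c1, the receptor gene, and crhb and pomca, the hormone genes of hypothalamus and pituitary, each called at 1 stage or at none. The list did not pass (camera adjusted p = 0.165).

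Over both stages 4887 genes and probes were called, 2156 higher and 2731 lower, 2898 of them named, and with slide as a block 1584, 857 higher and 727 lower. The split was 1764 higher and 4381 lower with median centring and 2270 and 4533 after normexp. Leaving out 1 array gave between 3388, without 24 hpf beclomethasone replicate 2, and 6775, without 24 hpf DMSO replicate 3. At each stage on its own, 565 were higher and 480 lower at both, 1045 in all where 248 would be expected for independent lists, and 118 were called with opposite signs. Fisher's test on the calls of the 2 stages without regard to sign gave an odds ratio of 4.24 (p = 1.70e-225). It counts genes and probes as independent. Both contrasts also share 1 spread per gene, so that genes of small spread are called at both more easily. Neither the expected number nor the p-value thus measures a shared response alone. With slide as a block the shared calls were 196, and they were between 603, without 24 hpf beclomethasone replicate 2, and 1450, without 24 hpf DMSO replicate 3, when 1 array was left out, with 646 and 676 without 72 hpf beclomethasone replicates 2 and 3. Of the 6247 called at either stage, 68.4% had the same sign at both, with a correlation of 0.40, and over all genes and probes the correlation was 0.15.

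The average rise was 3.53 ± 0.08 for hsd11b2 (adjusted p = 4.39e-08). Those of fkbp5 (adjusted p = 0.00253) and klf9 (adjusted p = 0.00122) were called, and their sizes are not given because of the dim DMSO signal at 24 hpf. Other average rises were 3.60 ± 0.27 for egln3, 3.24 ± 0.11 for stk35, 3.15 ± 0.28 for ddit4, 2.88 ± 0.12 for nr1d2a and 2.55 ± 0.10 for the carrier gene slc16a12b. The cytokine brake socs3a rose by 2.56 ± 0.20, pck1 by 2.21 ± 0.40 (adjusted p = 0.00444) and sgk1 by 0.98 ± 0.04. Falls were -1.74 ± 0.07 for abrab (adjusted p = 5.30e-07), -1.42 ± 0.20 for krt99, -0.96 ± 0.06 each for the helicase gene hells and the replication gene mcm10, -0.95 ± 0.07 for ccne1 and -0.92 ± 0.08 for the replication fork gene tipin. The other probe of mcm10 had -0.08 at 24 hpf and -0.20 at 72 hpf, and only 1 of its 2 probes was called at each stage. In the stress axis list 1 of 14 rose and 4 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.165). The falls were 0.33 ± 0.06 for nr3c1 (adjusted p = 0.00491), 0.33 ± 0.07 for crhb (adjusted p = 0.0122), 0.41 ± 0.11 for cyp17a1 (adjusted p = 0.0288), which fell at 72 hpf and differed between stages (-0.96), and pomca fell too (adjusted p = 0.0338), without a size since it was well above background on 1 of 3 arrays in each 24 hpf group. The Hedgehog target gli1 was not called (0.50 ± 0.17, adjusted p = 0.0658), nor were per1a (adjusted p = 0.739) and mmp9 (adjusted p = 0.821).

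Among lists, 18 of 22 receptor targets rose and 0 fell (18 and 1 adjusted over the list alone; camera adjusted p = 1.76e-18; adjusted p = 3.95e-04 with an estimated correlation). Of 30 clock genes 14 rose and 2 fell (15 and 3 adjusted over the list alone; camera adjusted p = 1.40e-05; adjusted p = 0.0245 with an estimated correlation). Protein turnover had 7 rises and 2 falls in 18 genes (8 and 2 adjusted over the list alone; camera adjusted p = 4.49e-04; adjusted p = 0.0405 with an estimated correlation). Of 19 chromatin genes 14 fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 1.73e-07; adjusted p = 0.0553 with an estimated correlation), with ezh2 at -0.69 ± 0.06 and dnmt1 at -0.58 ± 0.04. Of 34 cell cycle genes 18 fell and 0 rose (19 and 0 adjusted over the list alone; camera adjusted p = 4.88e-07; adjusted p = 0.113 with an estimated correlation).

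The comparison of 72 with 24 hpf in DMSO asks which genes development itself changed over these 2 days. Rises included those of rho, the rod photopigment, matn1 of cartilage and fabp10a of liver. Falls included those of the early globin gene hbbe3, prtga of the embryonic nervous system and the hatching enzyme gene he1.2.

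In DMSO 16589 genes and probes differed, 7362 higher and 9227 lower at 72 hpf, 8663 of them named, and at least 2-fold 4475 and 4090. With slide as a block 11306 were called, and leaving out 1 array gave between 15429 and 19001. Each array centred on its median moved the split to 5416 higher and 12105 lower, and normexp to 6458 and 13464, so that the balance of rises and falls depends on the scaling. The gene rho rose at least 2801-fold (adjusted p = 3.95e-08), matn1 at least 1248-fold and ampd1, a muscle enzyme gene, at least 1431-fold. The liver gene fabp10a rose by 8.35 ± 0.29 (adjusted p = 1.09e-08) and the synaptic gene snap25b by 5.31 ± 0.20. The hormone gene crhb, lower with treatment over both stages, was higher at 72 hpf by 3.59 ± 0.10. Falls were -7.79 ± 0.22 for hbbe3 (adjusted p = 3.82e-09), while hbbe2 rose by 4.28 ± 0.19, -6.24 ± 0.08 for prtga (adjusted p = 5.84e-11), -5.96 ± 0.11 for the ear gene oc90 and -5.46 ± 0.57 for he1.2.

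The lists that follow passed at the preset correlation. With an estimated one no list passed, and the lowest adjusted p over the 32 lists was 0.0594. Of 25 photoreceptor genes 23 rose and 0 fell (camera adjusted p = 1.32e-13), of 29 lens genes 24 rose and 1 fell (adjusted p = 1.67e-09), and of 28 glycolysis genes 26 rose and 1 fell (adjusted p = 4.77e-10). Of 32 neuron and glia genes 25 rose and 5 fell (adjusted p = 2.91e-07) and of 22 liver genes 18 rose and 1 fell (adjusted p = 8.18e-07). Of 34 cell cycle genes 0 rose and 32 fell (adjusted p = 3.85e-13), with rrm1 at -2.41 and cdc6 at -2.42, and of 19 chromatin genes 0 rose and 17 fell (adjusted p = 2.28e-06). Of 71 ribosomal genes 0 rose and 70 fell (adjusted p = 4.89e-14) and of 33 neural progenitor genes 4 rose and 27 fell (adjusted p = 1.69e-07), with notch1a at -3.48. The directions of the treatment at 24 hpf ran along those of development for part of the genes. The shift and the size of the stage difference were taken from different arrays. Of 4391 genes and probes higher at 72 hpf, 65.5% shifted up at 24 hpf relative to the median shift, and of 4017 lower at 72 hpf 69.1% shifted down. These had to pass the stage test on all arrays, the DMSO array of the shift included, which can raise both shares. Over all genes and probes, without that choice, the correlation was 0.23.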

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

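Most tests in this part were fixed before the result they measure was seen, and the tests of the opposite treatment labels and the count of splits by pairs were chosen after. A slope planned for the slide test is left out, since the arrays it compares had picked its genes.

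The results here were picked out because the effect of beclomethasone differed between 24 and 72 hpf by a test of the difference itself, and each value is 72 hpf minus 24 hpf. In all 1586 genes and probes differed. In 100 of the 200 splits of the treatment labels within the stages, drawn at random and the real one among them, 1 gave as many, and the highest other count was 839. The same splits gave as many shared calls at both stages as the 1045 found in 1 case and as many calls over both stages as the 4887 found in 1 case, the real ones. Splits of this kind undo the treatment groups too. They bear on a response of any sort, not on whether it differed between stages. The split with only the 72 hpf labels exchanged was not drawn. Its difference would equal the real average in all but scale and sign, and so call the same 4887, above the 1586. At a single stage 10 splits exist, too few for a share below 0.05, and the highest other counts were 3 at 24 hpf, 3 at 72 hpf and 0 between stages. For the number of lists that differed, 14, the splits gave as many in 15 of 100, so that chance could account for it. The replicate numbers pair the 72 hpf arrays, and among the 45 splits that part all 3 pairs, as the real one does, 5 gave as many lists. None of the other 44 reached the real count of genes, where the highest was 484.

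At the preset correlation 14 lists differed, and with an estimated correlation 0 did (lowest adjusted p = 0.170). Their mean shifts were those of receptor targets (0.38), glycolysis (-0.36), leukocyte markers (-0.12), cell cycle (-0.25), cell cycle inhibitors and p53 targets (0.31), protein turnover (0.48), skeletal muscle (-0.19), heart muscle (-0.23), liver (-0.042), erythroid genes (-0.67), ionocytes (0.051, but lower by camera), heat shock and the unfolded protein response (0.57), lipid and cholesterol metabolism (0.44) and ribosomal proteins (0.14).

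Genes of hormone and stress response with a difference in log2 fold change were sgk1 (0.81), hsd11b2 (-0.80), dusp1 (1.27), zbtb16a (1.06), cyp17a1 (-0.96), klf2a (1.54), nr4a1 (-0.72), rel (-1.43), nos2b (1.46) and mpx (-0.65). Genes of stress and protein folding were hsp90aa1.2 (1.59), hsp70l (1.19), hspa4a (1.40), dnaja1 (1.29), atf4b (0.89), chac1 (1.15), trib3 (1.07) and eif4ebp3l (0.40). Those of metabolism, transport and the clock were cyp8b1.3 (6.12), cyp2k6 (6.07), cyp1a (-1.61), rhcga (4.97), insig1 (1.29), cyp51 (1.11), igfbp1b (3.02), pfkmb (-1.55), gpia (-1.30), pgam1a (-0.75), uox (-1.38), plg (-0.68), gad3 (1.90), cry4 (-1.16), bhlhe41 (1.54) and nr1d2a (-1.29), where the values of cyp8b1.3 and cyp2k6 rest on 24 hpf signals not above background, and that of pth1a below on such signals in 72 hpf beclomethasone. Muscle, blood and vessel genes were tnni2b.2 (-3.65), tnni2a.4 (-1.30), tpma (-0.62), smyhc2 (-1.27), abrab (-1.60), actc1a (-1.06), myf5 (-0.91), gata1a (-2.16), cahz (-1.18), nt5c2l1 (-0.85), etsrp (-0.80), flt4 (-0.70) and kdr (0.72). Genes of skin, ionocytes, retina and signalling were evpla (1.66), krt92 (-0.71), foxi3a (-1.08), atp1a1a.3 (-1.12), pth1a (-1.22), itga6b (3.07), pde6ha (-3.35), sufu (0.52) and shhb (-0.43). Genes of replication and chromatin were mcm2 (-0.77), mcm3 (-0.54), mcm5 (-0.71), mcm6 (-0.62), mcm10 (-0.50), cdc6 (-0.63), dnmt1 (-0.47) and uhrf1 (-0.58), and others were b3gnt3.1 (-1.98), emp3b (-1.49), ntmt2 (-2.21) and stk35 (-0.93). Each value is that of the gene's brightest probe. For zbtb16a that probe had -0.23 at 24 hpf and was not called, while 1 other probe was called there as a rise. The probes of zbtb16a ranged from -0.23 to 0.44 at 24 hpf and from 0.70 to 0.83 at 72 hpf. Those of cyp1a ranged from 0.55 to 2.19 at 24 hpf, with 1 of 3 called, and from 0.58 to 0.71 at 72 hpf. Probes of smyhc2 ranged from -1.64 to 1.36 at 24 hpf and from 0.09 to 0.49 at 72 hpf. For mpx the ranges were -0.39 to 0.42 and -0.31 to -0.23, and for uhrf1 -0.89 to -0.16 and -0.74 to -0.55. For nr1d2a they were 2.12 to 3.52 and 2.23 to 2.43. Each of smyhc2, mpx, uhrf1 and nr1d2a thus has a probe that differed between stages in the other direction.

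The scanner files and the deposited table carry opposite treatment labels, and 1 set must be exchanged. If the scanner labels were exchanged, receptor targets would fall in the arrays they call beclomethasone, but 100% of the 29 calls of that list are rises there, which argues against it. In the table as labelled 3.03% of 33 such calls are rises, so that its labels are the likely ones to be exchanged. This rests on the known response of these genes to glucocorticoids, and no record of the samples was at hand.

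The slide block took the count at 24 hpf from 4831 to 891. Those 891 compare arrays of 1 slide, so that a difference between slides does not make them. For the other calls a slide effect in place of a treatment effect stays open. The beclomethasone array on the DMSO arrays' slide called 1309 genes alone against these, but it is 1 array. Fewer arrays could be the reason: 1 beclomethasone array against 3 DMSO arrays with no slide term gave between 464 and 1360 calls, a range that holds 891 and does not tell.

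Of the falls at 24 hpf, 378 were of dim genes, on which the raised signal of DMSO replicate 3 bears. Without that array 74.9% passed in the same direction and 85.1% of their median stayed (-0.76 after -0.90). The arrays left had helped to pick these genes, so that neither value tells a raised floor from a treatment effect, and both stay open.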

How the results depend on the processing

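The 4 alternatives with the joined table, without the uneven array (24 hpf DMSO replicate 3) with 72 against 24 hpf in beclomethasone arrays, and with the genes called at 1 stage only whose response differs counted again without the uneven array (1577 at 24 hpf and 852 at 72 hpf) were chosen after results were seen. The weaker signal over background of the uneven array limits what 24 hpf DMSO tells of dim genes. Where the text gives no cause for a change, the cause was not tested. Scan was not run apart from slide, since each slide was scanned at its own time. Of 453 results for single genes, 453 kept direction and side of the threshold with marked spots kept, 451 with trend and robust, 450 with every probe on its own, 438 with array weights, 432 without the uneven array, 431 with median centring, 428 after normexp, 420 after normexp with quantile normalization, 416 with no filter, 417 in the joined table, 403 with quantile normalization, 382 with the median over probes and 268 with slide as a block. Of those on only the groups compared 244 of 304 did, and under the stricter filter 251 of 252. Of 96 results for lists, 57 kept them with an estimated correlation, 78 with slide as a block, 74 with fry, 85 with quantile normalization and 86 without the uneven array. In DMSO 16589 genes and probes differed between stages, and in beclomethasone arrays 17017.

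With a replicate block 4846 were called at 24 hpf, 2513 at 72 hpf, 4926 over both stages, 1502 for the difference and 16676 between stages, with 1040 shared, 20, 11 and 13 lists and 408 of the named genes. With a replicate block within stage the counts were 4168, 2046, 4508, 848 and 14074, with 817 shared, 20, 12 and 12 lists and 387 named genes. At 24 hpf the check showed no pairing and could not exclude it, and with the block within stage 110 of the 128 calls named there passed. At 72 hpf, apart from the genes given with their values, the block within stage left nfil3-6 (adjusted p = 0.0729), fosab (0.0578), pgam1a (0.0691), dll4 (0.134), esama (0.0917), atp1a1a.3 (0.0691), cldni (0.0855) and hsp90aa1.1 (0.279) uncalled, and it changed no other named call there.

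Counts moved by over 1.5 times as follows. With a 2-fold minimum 575 were called at 24 hpf, 493 at 72 hpf, 335 over both stages, 439 for the difference and 8565 between stages, with 136 shared, because the minimum takes calls away. Array weights gave 4401 at 72 hpf, 7410 over both stages, 4011 for the difference and 1722 shared. Slide as a block gave 891, 766, 1584 and 67, with 196 shared and 248 of 429 named genes. Only the groups compared gave 1311 at 24 hpf and 428 shared. Of the named calls, 74 of 128 held at 24 hpf and 94 of 96 at 72 hpf. As many arrays were left out at both stages, so that fewer arrays alone do not account for the drop. The median SD was 0.21 in 24 hpf DMSO and 0.10 to 0.15 in the other groups. Many calls at 24 hpf thus rest on a spread shared with the 72 hpf arrays. Normexp gave 9656 at 24 hpf and 6023 for the difference, and with quantile normalization 2530 for the difference. For the difference, trend and robust gave 2457, no filter 1014, the stricter filter 2405 and the fit without the uneven array 3069. The stricter filter, with fewer genes tested, gave 9412 between stages, 13 lists at 24 hpf and 241 named genes. Lists at 24 hpf, 20 in all, were 1 with an estimated correlation and 13 in the table, as labelled or joined. At 72 hpf, where 11 passed, 5 did with an estimated correlation and 18 with every probe on its own, and for the difference 0 of 14 with an estimated correlation. In the table as labelled 69 named genes kept their call.

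Leaving out 1 array gave 2204 to 6309 calls at 24 hpf, 1512 to 2379 at 72 hpf, 3388 to 6775 over both stages, 663 to 3069 for the difference, 15429 to 19001 between stages, 603 to 1450 shared, 15 to 22, 9 to 15 and 9 to 16 lists, and 382 to 414 named genes.

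The table as labelled turned the sign of fkbp5 (-4.89 at 24 hpf, -4.40 at 72 hpf, -4.65 over both), hsd11b2 (-3.58, -3.11 and -3.35, and 0.47 for the difference), klf9 (-3.89, -3.51 and -3.70), sgk1 (-0.52, -1.37 and -0.94, and -0.85 for the difference), tsc22d3 (-1.17, -2.14 and -1.65, and -0.98 for the difference), pck1 (-2.74 at 72 hpf, -1.99 over both), crhb (0.45 and 0.18), pomca (0.89 and 0.50) and nr3c1 (0.42 at 24 hpf, 0.32 over both), because its labels are opposite. Of these values, those of fkbp5, klf9 and pomca at 24 hpf and over both stages rest on dim 24 hpf signals, with 1, 0 and 1 of 3 DMSO arrays well above background, and only their signs are meant. The stage difference of klf9 turned to 1.18 after normexp and 0.70 with quantile normalization in addition, and both sizes rest on a 24 hpf DMSO signal not above background. At 24 hpf these turned: ifnphi1 (0.12), rpl26 (0.042) and sagb (0.004) with quantile normalization, rps24 in the joined table and after normexp with quantile normalization (0.016 in both), mpx (-0.088 with the median over probes, -0.17 after normexp), stab1 (-0.14) and smyhc2 (-0.72, and -0.18 over both stages) with the median over probes. The ribosomal list at 24 hpf turned its mean or its direction by camera in the joined table (0.046), after normexp (-0.068), after normexp with quantile normalization (0.046) and with quantile normalization (0.058), and its difference between stages in the joined table (-0.034), after normexp with quantile normalization (-0.034) and with quantile normalization (-0.042).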

Other observations

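Groups not described so far did not pass as lists. At 24 hpf 2 of 18 genes of amino acid breakdown rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.216), 2 of 25 cartilage and bone genes rose and 0 fell (2 and 0; adjusted p = 0.227), 1 of 25 photoreceptor genes rose and 1 fell (1 and 1; adjusted p = 0.631), and 0 of 29 lens genes rose and 3 fell (0 and 2; adjusted p = 0.0976, and 0.0279 with slide as a block). Of 25 pancreas and intestine genes 2 rose and 1 fell (2 and 0; adjusted p = 0.634), of 33 neural progenitor genes 3 rose and 1 fell (1 and 0; adjusted p = 0.930), and of 32 neuron and glia genes 1 rose and 4 fell (1 and 4; adjusted p = 0.206, and 0.00639 with slide as a block). The list of cell cycle inhibitors and p53 targets passed with slide as a block (adjusted p = 0.0393).

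At 72 hpf 0 of 18 genes of amino acid breakdown rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.598), 2 of 33 neural progenitor genes rose and 0 fell (2 and 0; adjusted p = 0.0866, and 0.00983 with slide as a block), 1 of 32 neuron and glia genes rose and 0 fell (1 and 0; adjusted p = 0.340), and 1 of 16 segmentation genes rose and 1 fell (2 and 1; adjusted p = 0.226). Of 71 ribosomal genes 0 rose and 0 fell (adjusted p = 0.106, and 3.43e-04 with slide as a block). The lists without a call had camera adjusted p-values of 0.521 (heart muscle), 0.722 (cartilage and bone), 0.182 (photoreceptors), 0.529 (lens) and 0.890 (pancreas and intestine), and skeletal muscle had 0.704. For several lists the mean and camera, which sets a list against the other genes, differ in sign: at 24 hpf amino acid breakdown (mean -0.11, higher by camera), pancreas and intestine (-0.43, higher) and inflammation (-0.08, higher), whose means were 0.25, -0.01 and 0.02 without DMSO replicate 3, and at 72 hpf amino acid breakdown (0.15, lower). For immediate early genes at 24 hpf the mean was 0.09 and the median -0.07, and for genes handling foreign compounds the difference between stages had a mean of 0.38 and was lower by camera.

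A hypothesis for the higher erythroid, muscle, heart and liver lists at 24 hpf is that the embryos labelled beclomethasone were further in development, which predicts that genes higher at 72 hpf shift up and genes lower at 72 hpf shift down. With the shift and the size of the stage difference from different arrays, 65.5% of 4391 and 69.1% of 4017 did so relative to the median (medians 0.20 and -0.18). The shares were 66.4% and 70.9% for the pair of arrays on slide 1 alone, and at 72 hpf 54.4% of 4458 and 64.6% of 4294. All these genes had passed the stage test on all arrays, the DMSO array of the shift included, which can raise the shares. The erythroid list did not rise with stage in DMSO (7 of 17 genes rose and 7 fell, mean -0.17, camera adjusted p = 0.733). The prediction therefore does not extend to its higher level at 24 hpf. Some lists that rise with stage did not follow at 24 hpf: photoreceptor genes had a mean of -0.39 (-0.09 without DMSO replicate 3), lens genes of -0.28 (-0.14) and neuron and glia genes of -0.11 (-0.07). At 24 hpf the photoreceptor genes rho and opn1mw1 were well above background on 0 and 1 DMSO arrays and on 0 beclomethasone arrays. A shift of genes this dim could not be seen. The shift could come from older embryos for part of the genes, and a hormone that speeds development predicts the same shift, so that the test cannot separate them.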
